A study of Mus musculus with 30 samples.

How the data were processed

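The samples were brains of 30 mice aged 8 months, 10 wild type (WT), 10 carrying 1 intact copy of Tmem106b (HET) and 10 carrying none (KO), as the genotype label of each sample gives it. Tmem106b encodes a transmembrane protein of lysosomes and late endosomes, and its human counterpart is a risk gene for frontotemporal dementia. Per the labels' protocols, total RNA was taken from the cerebral hemispheres of all mice in a single extraction with the RNeasy Plus Mini kit, and sequencing libraries were made with the standard Illumina procedure. The labels also give the sex, a cohort number (1 or 2) and the RNA integrity number (RIN) of each mouse. Each genotype held 3 females and 3 males of cohort 1 and 2 females and 2 males of cohort 2. Replicate numbers were given here in the order of the samples and pair nothing. Each sample is a separate mouse, so the spread between samples is between animals. What the cohort number stands for, the strain, and the part of the gene that was targeted are not given in the sources used here.

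Reads were aligned with TopHat2 2.0.12 and Bowtie 1.1.0 against mm10, per the submitters' processing notes. The counting tool, the annotation release, the strand setting and any filter on genes are not given in the sources used here. The authors deposited a single table of 34871 genes by 30 samples, whose values are log2 RPKM (reads scaled to exon length and library size) after conditional quantile normalization, per the file's own name and header, with a column of gene lengths. Conditional quantile normalization is made to remove trends with gene length and GC content within each library and to bring the libraries close to each other. The highest value was 14.17 in every library and the library medians lay between 2.82 and 2.91, while the lower quartiles still ran from -1.20 to -0.07. The median over all genes, 2.85, is higher than plain log2 RPKM would give over so many genes, so the values served to compare libraries and not as absolute RPKM. Because the values are on a log2 scale already, no pseudocount was added, and fold changes are differences of deposited log2 values.

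The read depth of each library is unknown, since these normalized values carry no counts, and no counting interval can be given. Precision was therefore judged from the spread between mice. Without strand information, reads of a gene and of an overlapping or antisense neighbour cannot be told apart. Of 63 called genes that the rule below names for KO against WT, those not reported aside, 22 overlap another gene of the table, and the text gives the partner for some of them only. Coordinates are those of the table, on mm10, and 34248 of the gene identifiers were found in the reference annotation of that build used here. All sample columns were matched to a mouse by their titles. No rows of the mitochondrial chromosome were found in the table, so the list of mitochondrially encoded transcripts gave no value.

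All choices of test, samples, covariates, gene lists, named genes and alternatives were made before the data were examined, except where a later choice is named. Genes with a mean deposited value above 0 over the 30 libraries were kept, 23695 in all. The filter had been written as RPKM above 1, a reading that does not hold literally on the scale of these values. Each gene was fitted with a linear model in limma 3.58.1 (R 4.3.3) over all 30 libraries, with genotype, sex, cohort and RIN as terms, and tested with a two-sided moderated test (eBayes with an intensity trend). All 3 genotypes share the estimate of the spread. P values were adjusted by the Benjamini-Hochberg method over the genes kept, and a gene is said to rise or fall only at an adjusted p under 0.05. Contrasts were KO against WT, HET against WT, KO against HET, the slope over the number of deleted copies, and the interactions of KO against WT with sex and with cohort. Standard errors (SE) of fold changes are those of the fit. Values of groups are means with the standard deviation (SD) between mice.

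Gene lists for oligodendrocytes and myelin, other cell types of the brain, brain regions, lysosomal and stress pathways and technical checks were fixed in advance, and 35 lists had at least 3 genes kept. They were tested with limma's camera with its preset correlation between genes of 0.01, which compares a list with all other genes, and the p values were adjusted over the 35 lists. Camera with a correlation estimated from the data and fry, which tests whether a list's genes move one way on balance, were the alternatives. Members called are given over all genes and adjusted over the list alone. A list of glucocorticoid-induced genes was added after the KO against WT calls had been seen. Tmem106b was also tested in KO and in HET against WT by two-sided permutation with 100000 resamples.

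The genes named for each comparison follow a fixed rule. They are Tmem106b, the 12 largest rises and 12 largest falls among called genes, the called members and up to 4 members with the lowest p of each list described, the 5 genes with the lowest p where fewer than 5 were called, called genes within 10 Mb of Tmem106b, and Xist and Ddx3y as checks of the sex labels. Genes named outside the rule are said to be so. Some genes that the rule names are not reported here, in the text or the figure of list members, while counts and list tests include them.

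The fit was tested on simulated data built from the spread of these libraries, for KO against WT over 23695 genes with 200 genes of mean value above 4 changed in each of 5 runs. It recovered 18.8% of changes of 0.1 log2, 62.8% of 0.2, 84.4% of 0.3 and 96.4% of 0.5, and 5.98% of its calls were false. A list of 18 genes shifted by 0.1 log2 was called in 5 of 5 runs and an unchanged list in 0 of 5. Both lists were drawn at random, so they do not show how often the fixed lists, whose genes can vary together, are called without a change. In other groupings of the KO and WT samples, a median of 5 of the 35 fixed lists were called at the preset correlation.

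The alternatives were other covariates (genotype alone, without RIN, with the plate column of the sample title), no filter or a mean above 1, log2(RPKM + 1), quantile normalization, a common median, eBayes without the trend or with robust estimation, array weights, only the 2 groups compared, the mean of the neurons or striatum list as a covariate, each cohort and sex alone, and each KO and WT library left out in turn. A mean above 4 was added after seeing the data.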

Results

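Tmem106b RNA followed the genotype labels in all 30 brains. Its level was 9.17 ± 0.07 on the deposited log2 scale in WT (range 9.06 to 9.27), 8.58 ± 0.03 in HET (8.54 to 8.62) and 7.53 ± 0.08 in KO (7.43 to 7.67), as mean ± SD with n = 10 each. The ranges of the 3 genotypes did not overlap. In KO brains 32.0% of the WT level remained (95% interval 30.9 to 33.3), and in HET brains 66.3% (63.8 to 68.9). The fall was -1.64 ± 0.03 (log2 ± SE) in KO against WT (adjusted p = 3.51e-27, permutation p = 2e-05) and -0.59 ± 0.03 in HET against WT (adjusted p = 9.62e-15, permutation p = 1e-05, the lowest that 100000 resamples can give). The HET mean lay at 100.3% of the linear midpoint of WT and KO (bootstrap 95% interval 97.8 to 103.0). The fall was seen in each cohort (-1.65 in cohort 1, -1.64 in cohort 2) and each sex (-1.70 in females, -1.58 in males). The values are totals for the gene (chromosome 6, 13069759 to 13089269, mm10), so they do not show which part of the transcript remains in KO. Sex labels were checked with Xist, the RNA that silences 1 X chromosome in females (8.98 ± 0.22 in females and at most 0.89 in males, mean ± SD, n = 15 each). The Y-linked Ddx3y was 7.51 ± 0.20 in males and at most 0.26 in females. Both fitted the label of every mouse.

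**Figure D1:**
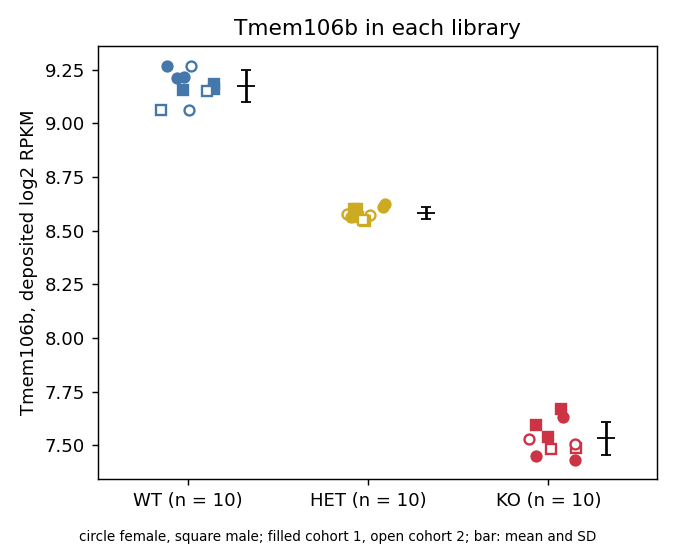
Tmem106b level (deposited log2 values) in each library by genotype, with the mean and SD of each group. Circles are females and squares males, filled symbols cohort 1 and open symbols cohort 2.

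KO brains held less RNA of oligodendrocyte and myelin genes than WT brains. The genes that fell include the myelin proteins Cnp, Mal, Cldn11 and Opalin, the myelin lipid enzymes Fa2h and Ugt8a, and Sox10, a transcription factor of the oligodendrocyte lineage. The falls were modest: the median change was -0.19 log2 over the myelin proteins, -12.6% on the linear scale, and it was seen in both cohorts and both sexes. Over all genes, 237 differed between KO and WT, 66 higher and 171 lower, with a median size of 0.19 log2, and 21 of them changed by more than 0.5 log2. Of 69 genes in 5 oligodendrocyte and myelin lists (myelin proteins, other mature markers, lineage transcription factors, newly formed oligodendrocytes and myelin lipid synthesis), 35 fell, 0 rose and 34 did not pass the test in limma (2846 of 23695 genes at an unadjusted p under 0.05). The list of oligodendrocyte precursors, with 0 of 9 called, is not among the 5. The 35 are 20.6% of the 170 falls other than Tmem106b. Cohort 1 alone gave 482 genes and cohort 2 alone 4, with 6 and 4 KO mice, females alone 13 and males alone 15. Of the 236 genes other than Tmem106b with the lowest p in cohort 1 alone, 65.7% had the same sign in cohort 2, a share that 16 of 100 simulations of unchanged groups reached. It was 69.9% from cohort 2 to cohort 1 (6 of 100), 78.8% from females to males (5 of 100) and 82.6% from males to females (1 of 100). The count is sensitive to covariates and libraries (144 with genotype alone, 114 with only the 2 groups in the fit, 138 without WT replicate 4, 388 without KO replicate 10). In simulated data the fit recovered 62.8% of changes of 0.2 log2 and 18.8% of changes of 0.1, so many changes of the size seen here can be missed.

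The myelin proteins list fell as a group: 14 of its 18 members fell, 0 rose and 4 did not pass over all genes, and 16 fell when adjusted over the list alone. Its camera adjusted p was 8.41e-33, and 0.000120 with an estimated correlation. Its mean was 8.93 ± 0.06 in WT, 8.85 ± 0.05 in HET and 8.71 ± 0.08 in KO (mean ± SD, n = 10). The median change was -0.20 in cohort 1, -0.22 in cohort 2, -0.23 in females and -0.17 in males. Opalin, a membrane glycoprotein of myelinating oligodendrocytes, fell most (-0.49 ± 0.08, adjusted p = 0.000525, below the WT mean in 10 of 10 KO brains, -0.55 in cohort 1, -0.40 in cohort 2). Cldn11, the tight junction protein between myelin layers, fell by 0.28 ± 0.03 (adjusted p = 1.29e-07, below every WT brain in 10 of 10, cohorts -0.24 and -0.32). Cnp, an enzyme of non-compact myelin, fell from 10.39 ± 0.06 to 10.10 ± 0.11 (adjusted p = 7.76e-06, below every WT brain in 10 of 10), and it overlaps Dnajc7 (0.0050). Mal changed by -0.31, the cytoskeletal protein Ermn by -0.31, the gap junction proteins Gjb1 and Gjc3 by -0.27 and -0.18, and Pllp by -0.21. Mog, a protein of the outer myelin surface, changed by -0.21 and Tspan2, which overlaps Tspan2os (-0.11), by -0.18. Mbp, a main protein of compact myelin, fell by 0.15 on the log2 scale and Mag by 0.14. Those that did not pass were Mobp (-0.11), Hapln2 (-0.16), Cd9 (0.02) and Omg (0.02).

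Other markers of mature oligodendrocytes were below WT in 21 of 21 members: 10 fell, 0 rose and 11 did not pass over all genes, and 19 fell when adjusted over the list alone. The median was -0.18 (adjusted p = 5.76e-29, and 0.000120 with an estimated correlation), with -0.20 in cohort 1 and -0.18 in cohort 2. Anln, a septin-binding cytoskeletal protein, fell by 0.33 ± 0.04 (adjusted p = 8.23e-05, below the WT mean in 10 of 10). The receptor Gpr37 changed by -0.27, the iron carrier Trf by -0.24 (it overlaps Gm20425, -0.18, called too), carbonic anhydrase Car2 by -0.21 and Ndrg1 by -0.20 (it overlaps Gm17035, -0.22, called too). Ppp1r14a fell too, at -0.29, as did Tmem88b at -0.23, the small heat shock protein Cryab at -0.22 and Sept4 at -0.12. Of the 10 transcription factors of the oligodendrocyte lineage, 5 fell, 0 rose and 5 did not pass, and 6 fell when adjusted over the list alone. Their median was -0.19 (adjusted p = 5.47e-11, and 0.000120 with an estimated correlation), with -0.22 in cohort 1 and -0.13 in cohort 2. Those that fell were Sox10 (-0.34 ± 0.05, adjusted p = 0.000613, below the WT mean in 10 of 10, -0.45 in cohort 1, -0.17 in cohort 2), Olig1 (-0.25), Nkx2-2 (-0.22), the myelin gene regulator Myrf (-0.20) and Nkx6-2 (-0.19). Under other processing, Nkx2-2 lost its call in 7 of 15 alternatives and Nkx6-2 in 2. Olig2 stood at -0.19 and did not pass (adjusted p = 0.0566).

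Enzymes and carriers of myelin lipids also fell: 5 of 11 fell, 0 rose and 6 did not pass over all genes, and 6 fell and 1 rose when adjusted over the list alone. The list's median was -0.10 (adjusted p = 3.01e-07, and 0.00347 with an estimated correlation), with -0.09 in cohort 1 and -0.10 in cohort 2. Fa2h, which hydroxylates the fatty acids of myelin galactolipids, fell by 0.39 ± 0.03 (7.34 ± 0.08 in WT, 6.95 ± 0.08 in KO; adjusted p = 2.70e-08, below every WT brain in 10 of 10, cohorts -0.41 and -0.36). Ugt8a, which makes galactosylceramide, fell by 0.39 ± 0.05 (adjusted p = 2.06e-05, 10 of 10, cohorts -0.41 and -0.37), and Gal3st1, which makes sulfatide from it, by 0.27 ± 0.04 (adjusted p = 0.000623, below the WT mean in 10 of 10). Elovl7 changed by -0.20 and the glycolipid carrier Gltp by -0.14. Kdsr, of sphingolipid synthesis, stood at 0.11 and Cers2 at -0.10, neither past the test over all genes. Cholesterol synthesis, the other lipid pathway of myelin, was not called (median 0.02, adjusted p = 0.680). It had 0 of 22 members called over all genes and 0 adjusted over the list alone (Idi1 0.07, Lss 0.08).

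Earlier stages of the lineage were not called as groups. Of 9 genes of newly formed oligodendrocytes, 1 fell, 0 rose and 8 did not pass, and 1 fell when adjusted over the list alone (median -0.01, adjusted p = 0.332). It is Enpp6, a choline phosphodiesterase of cells that start to myelinate, at -0.43 ± 0.07 (adjusted p = 0.000512, below every WT brain in 10 of 10, -0.39 in cohort 1, -0.49 in cohort 2). Of 9 genes of oligodendrocyte precursors, 0 were called over all genes and 2 fell when adjusted over the list alone (median -0.04, adjusted p = 0.0937; Pdgfra -0.10, C1ql1 -0.20). The list for nodes of Ranvier and paranodes was called lower at the preset correlation only (median -0.03, adjusted p = 0.0262, and adjusted p = 0.335 with an estimated correlation), with 0 of 12 members called over all genes and 0 adjusted over the list alone (Cntn2 -0.06, Cntnap1 -0.08).

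**Figure D2:**
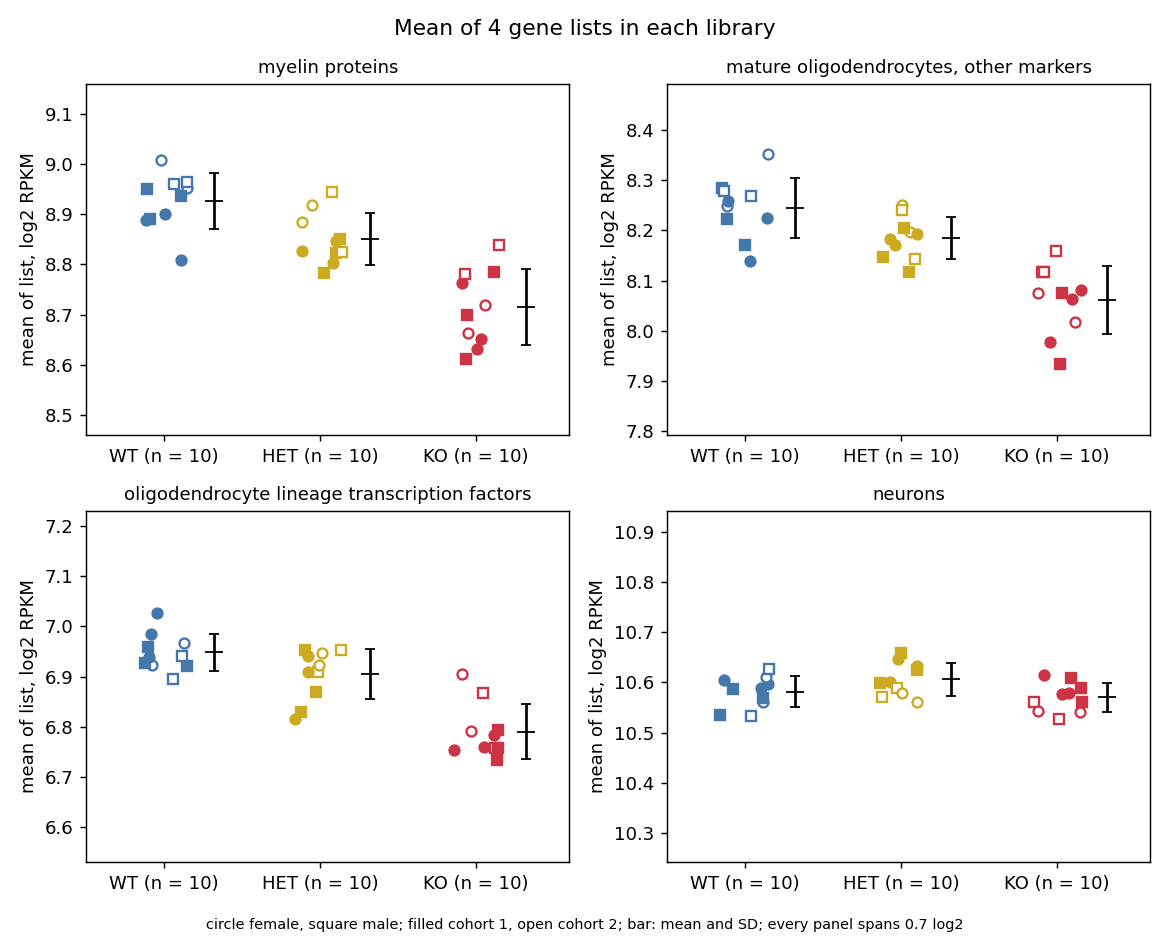
Mean of 4 gene lists (deposited log2 values) in each library by genotype; each panel spans 0.7 log2. Circles are females and squares males, filled symbols cohort 1 and open symbols cohort 2.

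**Figure D3:**
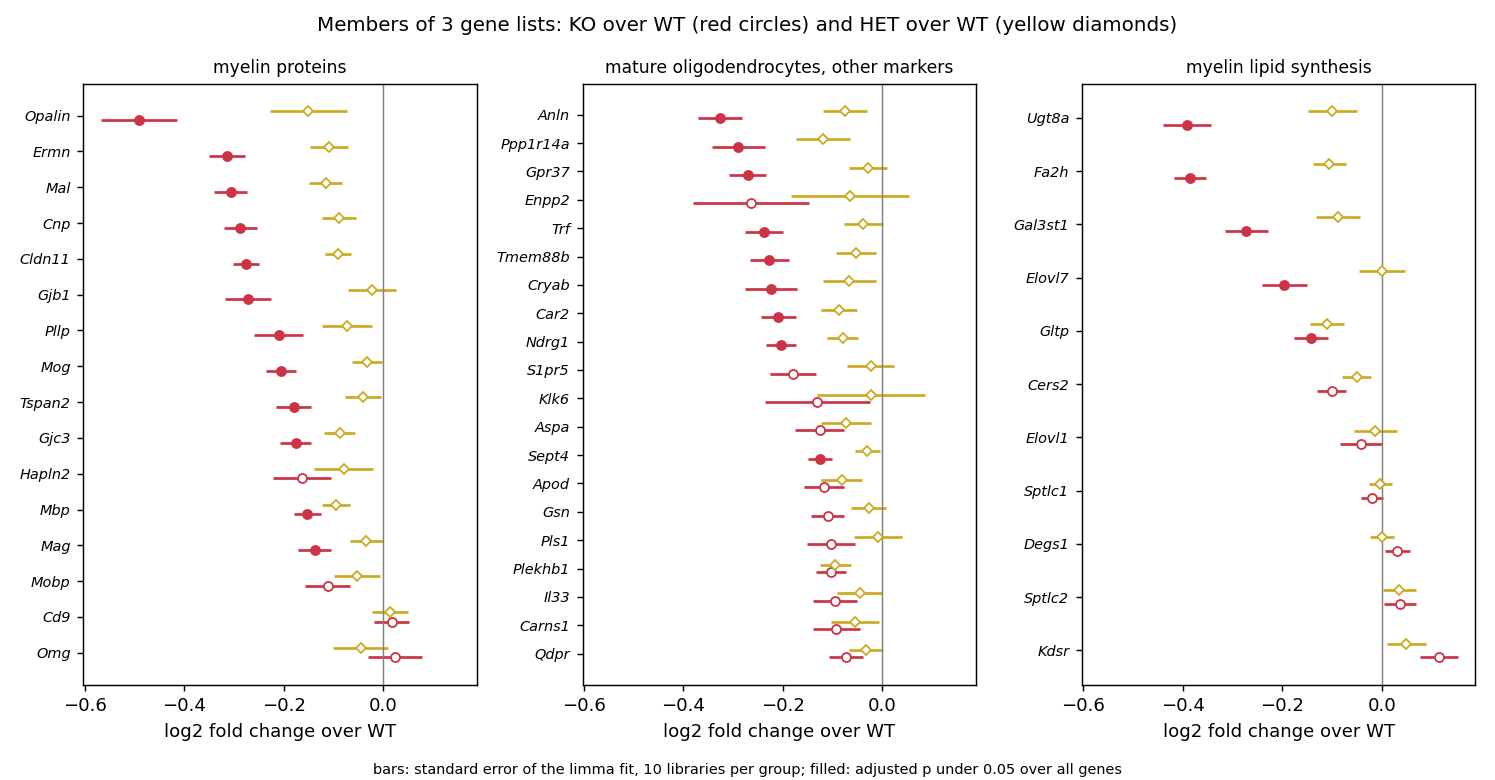
Log2 fold changes of the members of 3 oligodendrocyte and myelin lists in KO and in HET against WT, for the genes shown. Bars are standard errors and filled symbols mark an adjusted p under 0.05 over all genes.

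Markers of neurons were not called (median -0.01, adjusted p = 0.679), with 0 of 13 over all genes and 0 adjusted over the list alone (Syp 0.06, Thy1 -0.04). Their mean was 10.58 ± 0.03 in WT and 10.57 ± 0.03 in KO. The same held for excitatory neurons of the cortex and hippocampus (median -0.02, adjusted p = 0.659, 0 of 12 over all genes and 0 adjusted over the list alone, Nrgn -0.10). Among inhibitory neuron genes 1 of 12 rose over all genes and 1 adjusted over the list alone. The list was not called (adjusted p = 0.680), and its median was -0.01 while its mean, 0.04, and its test pointed up. The gene is Cort, the peptide cortistatin of a subset of interneurons, at 0.49 ± 0.11 (adjusted p = 0.0157, above the WT mean in 10 of 10, 0.65 in cohort 1, 0.24 in cohort 2).

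Among glial genes, Gfap and C1qb rose. Gfap, the intermediate filament of astrocytes, rose by 0.22 ± 0.05 (adjusted p = 0.00967, above the WT mean in 10 of 10, 0.13 in cohort 1, 0.36 in cohort 2). It was the 1 gene of 12 in the reactive astrocytes list to rise, with 2 adjusted over the list alone (C4b 0.18). That list had an adjusted p of 0.679, a median of -0.02 and a mean and test that pointed up. The astrocytes list was not called (adjusted p = 0.908, median 0.01 with the test pointing down). Of its members 0 of 17 passed over all genes and 1 was lower adjusted over the list alone (Sox9 -0.17). Of 20 microglia genes, 1 rose over all genes and 1 adjusted over the list alone (median 0.03, adjusted p = 0.679). It is C1qb, a chain of complement C1q, at 0.18 ± 0.04 (adjusted p = 0.0158, above the WT mean in 10 of 10, 0.21 in cohort 1, 0.15 in cohort 2). Genes of disease-associated microglia were called higher at the preset correlation only (median 0.13, adjusted p = 0.0188, and adjusted p = 0.242 with an estimated correlation). They had 0 of 16 called over all genes and 0 adjusted over the list alone (Clec7a 0.58, Ccl3 0.89), with a median of 0.19 in cohort 1 and 0.03 in cohort 2. Interferon response genes were not called (median 0.05, adjusted p = 0.680, 0 of 14 over all genes and 0 adjusted over the list alone, Ifit1 0.19, Oas1a 0.29).

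Among lysosomal genes, those of the compartment that holds TMEM106B, the subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, were slightly higher in KO. Their median was 0.03 (adjusted p = 0.0188, and 0.0407 with an estimated correlation), with 0.04 in cohort 1 and 0.01 in cohort 2. Of the subunits 0 of 18 were called over all genes and 3 higher adjusted over the list alone (Atp6ap2 0.06, Atp6v0d1 0.04, Atp6v0e 0.09). With a single library left out, the estimated-correlation adjusted p ran from 0.0220 to 0.106, so this call depends on which mice are in the fit. Lysosomal enzymes and membrane proteins were not called as a list (median 0.01, adjusted p = 0.649). Of 44, 1 rose over all genes and 1 adjusted over the list alone, the protease Ctsd, at 0.10 ± 0.02 (adjusted p = 0.00771, above the WT mean in 10 of 10, 0.09 in cohort 1, 0.10 in cohort 2). The autophagy list was not called (median 0.02, adjusted p = 0.968). Wipi1, which binds forming autophagosomes, was the 1 of 19 to fall, also adjusted over the list alone, at -0.16 ± 0.03 (adjusted p = 0.00311, below the WT mean in 10 of 10; -0.15 and -0.19 in the cohorts). Frontotemporal dementia genes and the TMEM106 family were not called (median 0.01, adjusted p = 0.57, 0 of 12 over all genes and 0 adjusted over the list alone, Sort1 -0.06). Genes of the unfolded protein response stood at a median of 0.00 (adjusted p = 0.679), with 0 of 16 over all genes and 1 higher adjusted over the list alone (Dnajb9 0.07, Herpud1 0.11).

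Immediate early genes, which follow recent neuronal activity, had a median of -0.41 and 12 of 13 below WT, called lower at the preset correlation (adjusted p = 2.64e-05, and adjusted p = 0.485 with an estimated correlation). Members called were 0 over all genes and 0 adjusted over the list alone (Fos -0.78 ± 0.31, Arc -0.66). The median was -0.62 in cohort 1 and -0.10 in cohort 2. In vascular cells, Tek, the angiopoietin receptor, was the 1 of 13 endothelial genes to fall (-0.21 ± 0.05, adjusted p = 0.0461, below the WT mean in 9 of 10, -0.34 in cohort 1, -0.04 in cohort 2). Adjusted over the list alone, 4 were higher and 5 lower, with no call for the list (median -0.05, adjusted p = 0.227). Mural cells were called lower at the preset correlation (median -0.07, adjusted p = 0.0416, and adjusted p = 0.363 with an estimated correlation), at 0.07 in females and -0.14 in males. Their members passed in 0 of 9 cases over all genes, and 1 was lower adjusted over the list alone (Pdgfrb -0.18). Meningeal fibroblasts were not called (median -0.05, adjusted p = 0.225, 0 of 10 over all genes and 2 lower adjusted over the list alone, Col3a1 -0.51, Dcn -0.16).

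Among markers of brain regions and adjoining tissue, C1ql2 fell and Tac1 rose. Choroid plexus genes were called lower at the preset correlation only (median -0.14, adjusted p = 0.0367, and adjusted p = 0.831 with an estimated correlation), at -0.43 in cohort 1 and 0.16 in cohort 2. In this list 0 of 13 passed over all genes and 0 adjusted over the list alone (Folr1 -0.34). Thalamus genes were called lower in the same way (median -0.05, adjusted p = 0.0416, and adjusted p = 0.335 with an estimated correlation), at -0.05 in cohort 1 and 0.01 in cohort 2. Here 0 of 8 passed over all genes and 1 was lower adjusted over the list alone (Tnnt1 -0.23). The lists for ependymal cells (median 0.05, adjusted p = 0.475, 9 genes), blood (0.10, 0.679, 5 genes), hypothalamus (0.02, 0.680, 10 genes; Pomc 1.02 ± 0.56) and olfactory bulb (-0.04, 0.721, 5 genes) had 0 called over all genes and 0 adjusted over the list alone. In the cerebellum list 0 of 8 passed over all genes and 1 was lower adjusted over the list alone (Pcp2 -0.18). Its adjusted p was 0.659, with a median of 0.02 while the mean, -0.03, and the test pointed down. In the hippocampus list (median -0.04, adjusted p = 0.30, 8 genes), C1ql2, a synaptic organizer of dentate mossy fibres, fell by 0.31 ± 0.05 (adjusted p = 0.00168, below the WT mean in 10 of 10, -0.36 in cohort 1, -0.25 in cohort 2). Adjusted over the list alone, 1 was higher and 1 lower. In the striatum list (median -0.00, test up, adjusted p = 0.679, 10 genes), Tac1, the substance P precursor, rose by 0.22 ± 0.05 (adjusted p = 0.0251, above the WT mean in 9 of 10, 0.31 in cohort 1, 0.08 in cohort 2), the 1 call over all genes and adjusted over the list alone. Genes that differ between C57BL/6 substrains were not called (median 0.01, adjusted p = 0.659, 0 of 6 over all genes and 1 higher adjusted over the list alone, Wdfy1 0.08). RIN was 9.40 ± 0.28 in WT, 9.23 ± 0.22 in HET and 9.35 ± 0.49 in KO. Of the 35 lists, 11 were called at the preset correlation, 5 with an estimated correlation and 5 by fry.

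**Figure D4:**
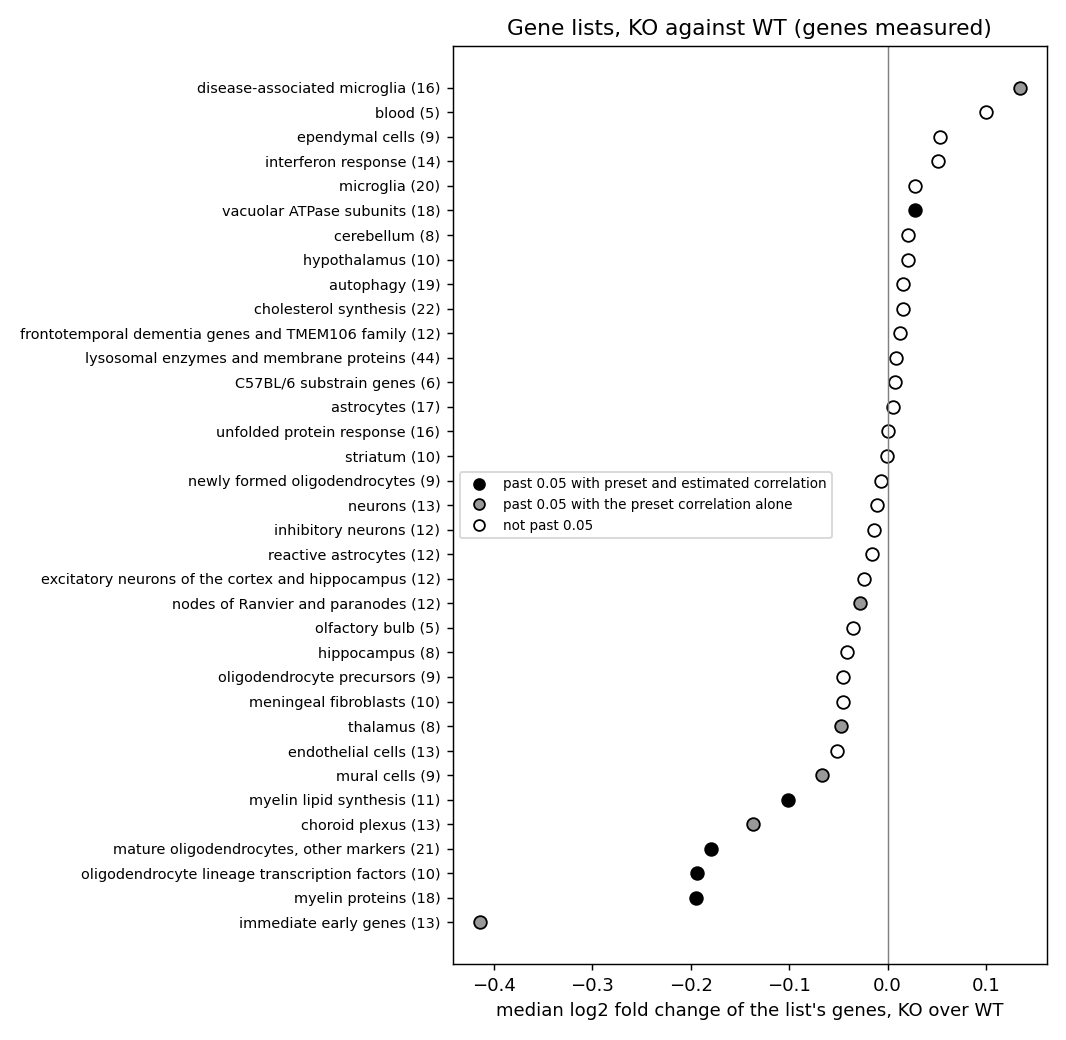
Median log2 fold change of each of the 35 gene lists in KO against WT. Shading shows whether the list was called at the preset correlation and with an estimated one.

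Of the called genes, 23 had a mean under 4, and most of the largest changes outside the lists are among these. Falls included Mir106b, a microRNA within Mcm7 (-1.53 ± 0.34, adjusted p = 0.0228; Mcm7 -0.029), Gm20430, which overlaps Lats2 (-1.09; Lats2 -0.033), 7630403G23Rik (-0.99 ± 0.19, adjusted p = 0.00537) and Gm13846 (-0.86). Others were the odorant receptor Olfr558 (-0.82), the steroid dehydrogenase Akr1c18 (-0.79), Nxf7 (-0.77), the keratin Krt2 (-0.54), the interferon-induced GTPase Gbp11 (-0.54) and Abhd12b (-0.47). Rises included Plin4, a lipid droplet protein (1.13 ± 0.24, adjusted p = 0.0133, above every WT brain in 9 of 10, 1.54 in cohort 1, 0.56 in cohort 2), Mslnl (0.98 ± 0.15, adjusted p = 0.000623; 1.44 in WT, 2.43 in KO) and the acid phosphatase Acp5 (0.90 ± 0.22). Higher too were the hypoxia-inducible factor Hif3a (0.88 ± 0.20, adjusted p = 0.0230, 1.33 in cohort 1, 0.25 in cohort 2) and the metallothionein Mt2 (0.46 ± 0.09, adjusted p = 0.00438, 0.68 in cohort 1, 0.14 in cohort 2). The entries of unnamed or small RNAs RP24-558H21.3 (1.41), RP23-133N19.3 (1.27), Mir709 within Rfx1 (1.25, with Rfx1 at -0.015), DQ267101 within Rian (1.24, with Rian at 0.033), A730020M07Rik (1.01) and Gm12996 (0.95) rose too. Reads at Mir106b, Mir709 and DQ267101 cannot be told apart from those of the genes that hold them, so a change of the small RNAs themselves is not shown. Within 10 Mb of Tmem106b, 2 of 87 genes other than Tmem106b itself were called, 2.30% against 0.991% elsewhere. They are Tac1 and Thsd7a, a thrombospondin-domain gene at 12311610 to 12749410 on chromosome 6, which fell by 0.20 ± 0.03 (adjusted p = 0.000623, below the WT mean in 10 of 10, -0.16 in cohort 1, -0.27 in cohort 2).

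In brains with 1 intact copy, Tmem106b was the 1 gene called (limma; 1497 of 23695 genes at an unadjusted p under 0.05). Genes with the next lowest p, none past the test, were 1700010K24Rik, which overlaps Psma5 (-1.55, adjusted p = 0.0703, with Psma5 at 0.08), Gm13205 in Casz1 (-0.32, adjusted p = 0.0703, with Casz1 at -0.047), Gm12996 (1.02), Olig1 (-0.20, adjusted p = 0.286) and RP23-27L18.4 (0.39). Over the 69 genes of the 5 oligodendrocyte and myelin lists the median was -0.05 in HET and -0.16 in KO, and 58 were below WT in HET and 59 in KO. In simulated unchanged groups 34.3 were below WT in HET on average, and 1 of 100 simulations had as many as 58 and 1 a HET median as far from 0. Both comparisons use the same WT brains, so the HET and KO figures are not independent. At the preset correlation 11 of 35 lists were called, 3 higher and 8 lower. None (0) held with an estimated correlation and 1, the vacuolar ATPase, by fry (adjusted p = 0.0290), and 0 members of any list were called over all genes. Other covariates or log2(RPKM + 1) gave up to 4 genes.

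The myelin proteins list had a median of -0.08 in HET (adjusted p = 7.57e-08, and adjusted p = 0.107 with an estimated correlation), with 6 lower adjusted over the list alone (Mal -0.11, Cldn11 -0.09, Mbp -0.09, Ermn -0.11). Other mature oligodendrocyte markers were below WT in 21 of 21 (median -0.05, adjusted p = 1.79e-05, and adjusted p = 0.180 with an estimated correlation, 0 adjusted over the list alone; Plekhb1 -0.09). The lineage transcription factors (median -0.04, adjusted p = 0.0211, and adjusted p = 0.180 with an estimated correlation) had 2 lower adjusted over the list alone (Sox10 -0.16). Myelin lipid synthesis (-0.01, adjusted p = 0.0449, and adjusted p = 0.332 with an estimated correlation) also had 2 (Gltp -0.11, Fa2h -0.11). Lower at the preset correlation were also microglia (-0.06, adjusted p = 0.000127, and adjusted p = 0.372 with an estimated correlation; Cx3cr1 -0.11) and mural cells (-0.11, adjusted p = 0.000127, and adjusted p = 0.107 with an estimated correlation, 3 lower adjusted over the list alone; Rgs5 -0.11, Higd1b -0.23). The same holds for meningeal fibroblasts (-0.11, adjusted p = 0.00394, and adjusted p = 0.372 with an estimated correlation; Dcn -0.12) and lysosomal genes (-0.02, adjusted p = 0.0468, and adjusted p = 0.372 with an estimated correlation; Galc -0.05). Higher at the preset correlation were the vacuolar ATPase (0.02, adjusted p = 0.0211, and adjusted p = 0.107 with an estimated correlation, 2 higher adjusted over the list alone; Atp6v1b2 0.04, Atp6ap2 0.06), inhibitory neurons (0.04, adjusted p = 0.0211, and adjusted p = 0.180 with an estimated correlation; Cort 0.31) and immediate early genes (0.14, adjusted p = 0.0449, and adjusted p = 0.733 with an estimated correlation; Egr1 0.25). In the microglia, meningeal, lysosomal, inhibitory neuron and immediate early lists 0 members passed adjusted over the list alone.

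KO and HET brains differed in 28 genes, 7 higher and 21 lower in KO (2052 of 23695 at an unadjusted p under 0.05), and 25 of the 28 were also called in KO against WT. Of the 69 oligodendrocyte and myelin genes, 12 fell from HET to KO. Among them, Fa2h changed by -0.28 ± 0.03 (adjusted p = 3.88e-05), Ugt8a by -0.29 ± 0.05 (adjusted p = 0.00436), Cldn11 by -0.19, Cnp by -0.20, Mal by -0.19, Anln by -0.25, Gjb1 by -0.25, Gpr37 by -0.24, Trf by -0.20, Ermn by -0.20 and Mog by -0.17. Outside the lists fell Gm13846 (-1.05), the lipid transporter Abca8a (-0.28), Galnt6, which overlaps Galnt6os (-0.26, with Galnt6os at -0.29), the lysophosphatidic acid receptor Lpar1 (-0.24) and the tubulin Tuba8 (-0.22). The 7 rises were Mslnl (0.82), complement C4b (0.29 ± 0.05, adjusted p = 0.0142), Gfap (0.26 ± 0.05, adjusted p = 0.00533), carbonic anhydrase Car4 (0.18), Farp1 (0.15), Tada2a (0.13) and Ctsd (0.10). Tmem106b itself fell by 1.05 (adjusted p = 1.21e-21). The count was 12 with the mean of the neurons list as a covariate, 43 with array weights, and 44 with a mean above 4, a filter chosen after seeing the data.

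Over the number of deleted copies, 241 genes had a slope, 67 upward and 174 downward (2852 at an unadjusted p under 0.05), and 228 of them were called in KO against WT. With equal numbers of mice per genotype, the HET brains carry almost no weight in the estimate of a slope. These calls therefore largely repeat KO against WT and are no separate evidence of an effect of dose. Tmem106b changed by -0.82 per copy, Opalin by -0.25 ± 0.04 (adjusted p = 0.000567), Mir106b by -0.77, Akr1c18 by -0.40 and Nxf7 by -0.39. Plin4 rose by 0.57 ± 0.12 per copy (adjusted p = 0.0161), Mslnl by 0.49 ± 0.08 (adjusted p = 0.00154), Hif3a by 0.44 and Cort by 0.25. The slope alone called, among the named genes, Gm11750 (0.60), GBP11 (-0.26, a separate entry that overlaps Gbp11) and A730090H04Rik (-0.25). With genotype as the one term the count was 142.

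KO against WT and HET against WT share their WT brains, so their fold changes are correlated by construction. Across 15021 genes the correlation was 0.529, beside a mean of 0.503 (maximum 0.789) over 100 simulated sets of unchanged groups with shared controls, and 0.109 when the WT brains were split between the comparisons (50 splits). The covariance was 0.00291 against 0.00201 simulated, a difference of 0.000898, and 0.000811 with split controls. The sign was shared by 68.4% of genes, against 66.6% simulated and 53.8% with split controls. Genes are not independent replicates in these figures. Of the 236 genes called in KO other than Tmem106b, 95.8% had the same sign in HET. This is no evidence of a shared effect by itself: in the simulated unchanged groups the 236 genes with the lowest p shared it in 92.7% on average, and 36 of 100 simulations reached the real share. With split controls the share for genes selected in this way was 75.7% (median of 50 splits).

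The effect of losing both copies was not shown to differ between the sexes for any gene (limma; 0 called, 1682 of 23695 at an unadjusted p under 0.05). The lowest p values, none past the test, were those of Cbx6 (0.22, females minus males, adjusted p = 0.174), Ctif (0.20), Gm12951 (-3.00), Zfp410 (-0.25) and Dnm1l (-0.16), and for Tmem106b the difference was -0.11 (adjusted p = 0.686). Of the 69 oligodendrocyte and myelin genes 0 were called, with a median difference of -0.04. At the preset correlation 5 of 35 lists were called, and 0 with an estimated correlation or by fry. They were excitatory neurons (0.07, adjusted p = 0.0187, and adjusted p = 0.719 with an estimated correlation), endothelial cells (0.12, adjusted p = 0.0321, and adjusted p = 0.719 with an estimated correlation) and mural cells (0.17, adjusted p = 0.00349, and adjusted p = 0.343 with an estimated correlation), with choroid plexus (-0.35, adjusted p = 0.00163, and adjusted p = 0.719 with an estimated correlation) and interferon response (0.19, adjusted p = 0.0187, and adjusted p = 0.739 with an estimated correlation). Adjusted over the list alone, 4 excitatory neuron genes were higher, and 0 genes of the other 4 lists passed. With 5 mice per sex and genotype, an interaction has to be larger than a pooled difference to be called.

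The effect differed between the cohorts for 8 genes (2020 of 23695 at an unadjusted p under 0.05), and Tmem106b was not among them (difference 0.01). Cldn5, the tight junction protein of brain endothelium, was -0.80 in cohort 1 and 0.09 in cohort 2 (difference 0.90 ± 0.16, adjusted p = 0.0338), the basement membrane collagen Col4a1 -0.33 and 0.22 (0.55 ± 0.09, adjusted p = 0.0116), and the matrix metalloprotease Mmp14 -0.64 and 0.26 (0.895, adjusted p = 0.0116). Vstm4 was -0.60 and 0.16, the growth factor Igf2 -0.31 and 0.41, the RNA-binding Zfp36l1 -0.37 and 0.12, and Tprkb -0.14 and 0.08. The flavin monooxygenase Fmo2 went the other way, 1.08 in cohort 1 and -0.35 in cohort 2 (difference -1.44 ± 0.26, adjusted p = 0.0338). Cohort 2 held 4 mice per genotype. Another grouping of the same samples called 222 genes, so the count of 8 does not exclude chance by itself.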

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

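The tests of the spread between myelin genes, of Tmem106b and of the 10 Mb interval were chosen after the results were seen; the tests of regions, of substrain genes and of other groupings were chosen before.

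Single libraries far from the other 9 of their group were looked for in 339 groups of the named called genes and of all 35 lists. There were 26 (7.67%), where chance flags about 1 in 20 groups. Among them, with the nearest other library in brackets, were Nxf7 3.28 in HET replicate 4 (2.56), Abhd12b 2.45 in HET replicate 5 (2.87), Anln 6.80 in WT replicate 1 (6.93), Cnp 10.25 in WT replicate 3 (10.37), Trf 10.43 in HET replicate 3 (10.59), Tmem88b 8.05 in KO replicate 3 (8.31), Thsd7a 6.14 in HET replicate 2 (6.03), Sept4 9.30 in KO replicate 9 (9.42) and Lpar1 6.18 in KO replicate 3 (6.42). Plin4 stood apart in HET replicate 10 (4.23, next 3.26) and KO replicate 3 (5.84, next 4.19). The mean of the choroid plexus list was low in WT replicate 10 (4.72, next 5.28) and KO replicate 5 (4.49, next 5.01). The mean of the blood list was low in WT replicate 7 (7.94, next 8.85) and high in KO replicate 9 (11.63, next 9.46). Region lists stood apart for the striatum in WT replicate 2 (7.84, next 8.10), hypothalamus in HET replicate 4 (4.47, next 5.30), hippocampus in WT replicate 6 (4.78, next 4.91) and HET replicate 10 (5.14, next 5.03), cerebellum in KO replicate 4 (8.63, next 8.82) and olfactory bulb in HET replicate 9 (5.42, next 5.02). So did the reactive astrocytes list in HET replicate 8 (5.16, next 4.70), the lysosomal enzymes and membrane proteins list in HET replicate 2 (7.84, next 7.81) and the substrain genes list in KO replicate 5 (6.31, next 6.20).

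The KO effect differed between the cohorts, by a test of the interaction, for Fmo2 (-1.44, cohort 2 minus cohort 1), Tprkb (0.23), Zfp36l1 (0.49), Col4a1 (0.55), Igf2 (0.71), Vstm4 (0.77), Mmp14 (0.895) and Cldn5 (0.90). A difference between the sexes, females minus males, was called at the preset correlation only for 5 lists. They are excitatory neurons (0.066), endothelial cells (0.12), mural cells (0.17), choroid plexus (-0.35) and interferon response (0.19). With an estimated correlation or by fry 0 were called, so a difference is not shown.

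Each result was set beside 100 groupings of the same samples, the real one included. For KO against WT 1 of 100, the real grouping itself, called as many genes as the real 237 (highest other 1). That is the lowest share that 100 groupings can give, so chance is argued against but not excluded. The slope over copies also gave 1 of 100 (real 241, highest other 3), but it largely repeats KO against WT and is no separate result. Chance is argued against in the same way for the lists called with an estimated correlation (1 of 100, real 5, highest other 3). The same holds for the median of the myelin proteins list (1 of 100, real -0.19, highest other 0.144 in size). Chance stays open for the number of lists at the preset correlation. In KO 7 of 100 reached the real 11 (highest other 13), and in HET 6 of 100 reached the real 11 (highest other 14). In the sex interaction 48 of 100 reached the real 5 (highest other 13). Chance also stays open for the number of genes in HET against WT (8 of 100 reached the real 1, highest other 4). That 1 gene is Tmem106b, whose own test argues against chance (permutation p = 1e-05). No sex interaction gene was called, so 100 of 100 groupings reach the real 0 by definition and this count tests nothing (highest other 14). For KO against HET 2 of 100 reached the real 28, few enough by the rule set in advance. The other one called 137 genes, so the count by itself does not exclude chance. The group of 10 in that other grouping held 4 KO and 6 HET mice, 7 of them male and 5 of cohort 2. For the cohort interaction 2 of 100 reached the real 8, also few enough by that rule. The other one called 222 genes and set KO replicates 4, 8, 9 and 10 apart, 3 of them really of cohort 2. KO replicate 8 is labelled cohort 1. On the second principal component, described below, it stood at 6.68, beside a cohort 2 mean of 7.30 ± 4.57 (SD). The next highest cohort 1 library, HET replicate 9, stood at 1.05. Whether its cohort label is right was not tested, and all values for 1 cohort rest on these labels. The count of 8 does not exclude chance by itself either. Why these groupings called so many genes was not tested.

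Oligodendrocyte and myelin genes were lower in KO. A different share of a brain region in the KO samples is argued against for the cerebellum, hypothalamus and striatum: with the mean of each region list as a covariate in turn, the myelin proteins list kept at least 94.7% of its median (adjusted p at most 0.00103 with an estimated correlation). The thalamus, hippocampus and olfactory bulb lists were followed by at most 1 gene each, so these regions, and the share of white matter in the dissection, stay open. The same smaller share of all oligodendrocyte RNA in every KO brain would lower genes of these cells alone by the same amount. Here 10 myelin proteins differed from each other by more than under permuted labels (-0.11 to -0.49, permutation p = 0.00043, and 0.00465 without Opalin). This argues against such a share as the whole cause only if the 10 are expressed in oligodendrocytes alone and alike among them, which was not tested. Fewer oligodendrocytes, less RNA of some genes per cell, or both could therefore not be told apart. A biological effect of the genotype stays among the open explanations.

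Tmem106b RNA was left in KO. Mislabelled or mixed mice are argued against: 0 KO libraries lay within the range of the WT or HET libraries. What the remaining reads are (a transcript of the targeted allele, or reads of another source) was not tested, since the values are gene totals.

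Thsd7a, a neighbour of Tmem106b, was lower in KO, and its own limma test argues against chance for the fall (adjusted p = 0.000623). Whether other strain's DNA kept around the targeted locus lies behind it cannot be told, since it is open whether calls gather there: 2 of 87 genes within 10 Mb were called against 234 of 23607 elsewhere (Fisher's exact p = 0.215; 95% interval of the share inside 0.280% to 8.06%). A difference of C57BL/6 substrain between the groups cannot be told either: 0 of 6 substrain genes were called, but the bounds of their 95% intervals reached 0.479 log2, for Crb1, a gene of low values (0.241 for the next, Fgfbp3). An effect of the lost gene on its neighbour stays open and was not tested.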

How the results depend on the processing

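The filter at a mean above 4 was chosen after seeing the data, all other alternatives before. The library depth is unknown, so what depth limits cannot be given, and low genes rest on the spread between mice. Under the alternatives for processing, 0 of the named called values reversed, and 0 lists called in the main fit or the alternative. In 9 cases the median of a list called in neither turned its sign. Of 112 named called values, between 83 (mean of the neurons list as a covariate) and 112 (a common median) kept their call in fits of all 30 libraries with the same filter, and 60 of 87 with only the 2 groups compared. The myelin proteins, mature oligodendrocyte, lineage transcription factor, myelin lipid and vacuolar ATPase lists kept their call in 17 of 17 such alternatives, 1 of which leaves out the HET libraries. In subsets the vacuolar ATPase list kept it in cohort 1 alone (adjusted p = 0.0212) and lost it in cohort 2 (0.542), females (0.173) and males alone (0.113), and the myelin lipid list lost it in males alone (0.0849). Among the genes the text names, calls were lost most often in KO against WT for Nkx2-2 (7 of 15), Gm13846 (6 of 13), A730020M07Rik (6 of 14), Tek (5 of 15), Mag (4 of 15) and Gm20430 (4 of 14). In KO against HET it was Ctsd (6 of 15), and for the slope Gm11750 (10 of 13), A730090H04Rik and Acp5 (9 of 13 each). No paired analysis was possible because the labels carry no replicate numbers.

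Genes called in KO against WT (237) were 144 with genotype alone, where the cause was not tested. With fewer samples they were 114 with only the 2 groups compared, 4 in cohort 2 alone, 13 in females alone and 15 in males alone, yet 482 in cohort 1 alone, where the cause was not tested. Leaving out 1 library gave 138 (WT replicate 4) to 388 (KO replicate 10), and no other omission moved the count by over 1.5 times. HET against WT (1) gave 4 with genotype alone, 3 without RIN, 2 on log2(RPKM + 1) and 3 with the mean of the neurons list as a covariate. KO against HET (28) gave 44 at a mean above 4, where fewer genes are tested, 43 with array weights and 12 with the mean of the neurons list as a covariate. The slope (241) gave 142 with genotype alone. For these too the cause was not tested.

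Lists called in KO against WT (11) were 6 at a mean above 4, 4 in males alone, 5 with an estimated correlation and 5 by fry. Leaving out 1 library gave 6 (KO replicate 8) to 12, with 7 without WT replicate 7. In HET against WT (11) they were 0 with an estimated correlation and 1 by fry, and for the sex interaction (5) 0 and 0. Over the left-out libraries the median of the myelin proteins list ran from -0.21 to -0.18, with an adjusted p of at most 0.000478 with an estimated correlation. Among lists called in the fit of all libraries, in the subset or in both, the median turned its sign 8 times. In cohort 2 alone it did so for cholesterol synthesis (-0.038), reactive astrocytes (0.22), meningeal fibroblasts (0.22), choroid plexus (0.16) and thalamus (0.0072). In females alone it did so for mural cells (0.067), thalamus (0.017) and cerebellum (-0.094). In 30 further cases in 1 cohort or sex alone, the sign turned for a list called in neither fit. These subsets hold fewer samples, and the cause was not tested.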

Other observations

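The list of glucocorticoid-induced genes was chosen after the KO against WT calls had been seen, and its test was set before the list's values were.

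Sex and cohort took more of the first 2 axes of variation than genotype did. Between the cohorts 4150 genes differed (1917 higher and 2233 lower in cohort 2), and between the sexes 79, of which 28 lie on X or Y. The first principal component of 15022 genes held 21.3% of the variance and followed sex (92.4% of its variance), the second held 14.1% and followed cohort (64.8%), and genotype took at most 19.4% of the variance of any of the first 4. Genotype took more than sex or cohort of the third (19.4% against 0.2% and 6.7%) and of the fourth (18.7% against 1.2% and 0.7%). The share that RIN took was not computed, so genotype is not shown to be the main source of either. On the third, KO replicates 7 and 9 (RIN 8.5 and 8.9) stood at -10.4 and -8.81, and KO replicate 4 (RIN 10) at 11.9. KO replicates 3 (RIN 9) and 8 (RIN 9.8) went against that order, at 5.24 and 2.74. The lower quartile of all values was -0.26 ± 0.09 in females and -0.84 ± 0.22 in males (mean ± SD, n = 15 each).

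Mt2, Hif3a and Plin4, which glucocorticoids induce in several tissues, were higher in KO, and a hypothesis is that the KO mice had more glucocorticoid signal. The mean of 14 other glucocorticoid-induced genes differed by 0.08 between KO and WT (95% interval -0.06 to 0.21, permutation p = 0.273), by 0.16 in cohort 1 and -0.03 in cohort 2. Of the 14, 1 was called, Zbtb16 (0.36, adjusted p = 0.0196), with Fkbp5 at 0.30 (adjusted p = 0.107). Between mice, with genotype, sex and cohort fitted out, the mean of the 14 genes followed the mean of Mt2, Hif3a and Plin4 (correlation 0.805). That shows genes that vary together between mice, not a difference between KO and WT. The test of KO against WT does not decide, as the interval holds both 0 and changes of 0.2.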
